A study of Mus musculus with 29 samples.

How the data were processed

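RNA from fluorescently sorted cortical cells of postnatal mice was sequenced as bulk libraries. Per the labels' protocols, tissue pieces of pooled brains were dissociated with papain, labelled cells were purified by fluorescence-activated sorting, cells of consecutive experiments were pooled, and libraries were made with a low-input SMARTer kit. Replicates are therefore libraries of pooled animals, not single mice. The labels describe 29 samples in 9 groups, and the deposited table has 26 columns of values, each matched to its samples by the column names in their descriptions. In 2 columns the sequencing fractions of 1 library were pooled by the authors, 2 samples in PV P5 replicate 2 and 3 in pyramidal P12 replicate 3.

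The deposited values are FPKM (fragments scaled to transcript length and to the mapped fragments of each library), made by the authors. Per the submitters' processing notes, FastQC, TopHat2 and Cufflinks were used with the genome builds NCBIM37 and mm9. Those notes give no versions, roles, annotation or filters, and any further scaling between libraries is not stated. The table lists 37980 genes by Ensembl identifier and symbol, with 34616 distinct symbols and no coordinates, so no positions are given here. The annotation at hand belonged to another build and served only for gene names, chromosomes and the order of neighbouring genes.

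Read counts were not used here. Summed FPKM per library ran from 466208 to 633202, and 12331 to 13930 genes reached 1 FPKM. Relative depth was estimated from the low values of 967 single-exon genes of 800 to 1200 nt, taking the lowest 10 percent point of FPKM times length above 0 as 1 fragment. It ran from 17.9 to 44.4 fragments per FPKM and kilobase. Since these are not counts, no counting intervals are given, and a value of 0 is reported as listed at 0.

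The 2 oligodendrocyte columns held 21422 genes detected in either, and 9 of these were detected in 1 column alone, against 3482 to 4389 in the 24 other pairs of replicates. Over 6686 genes at 10 FPKM or more the SD of their log2 ratio was 0.135, against 0.3 to 0.707 in the other pairs. They were therefore averaged and counted as 1 library. That left 25 libraries, 3 in each of 8 groups and 1 of oligodendrocytes. All groups entered a single linear model fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with trend) on log2(FPKM + 1). Genes with at least 1 FPKM in at least 3 libraries were kept, 16398 of them, and 21582 were left out. The model has 16 residual degrees of freedom, and the median prior degrees of freedom were 4.28. P-values are two-sided and adjusted by Benjamini-Hochberg over all tested genes of a comparison, with a threshold of 0.05. A fold change is on the log2(FPKM + 1) scale, which understates the change of genes with low values. Genes called higher in 1 subtype than in each of the other two passed that threshold in both pairwise comparisons with a log2 difference of at least 1.

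The groups, comparisons, model, lists and most alternatives were chosen before the data were examined. There were 28 gene lists with 500 members written, 496 of them in the table: study candidates, SST interneuron markers, PV basket cell markers, chandelier cell markers, MGE interneuron core, CGE interneuron markers, pyramidal neuron markers, oligodendrocyte lineage, astrocyte, microglia, and endothelial and mural markers, red blood cell transcripts, sex-linked genes, dissociation and immediate early genes, cell cycle genes, immature and migrating neuron genes, presynaptic vesicle machinery, synaptic adhesion and organizers, axon guidance, protocadherins and cadherins, axon initial segment and node genes, potassium and HCN channels, GABA receptor subunits, glutamate receptor subunits, neuropeptides, perineuronal net and matrix genes, the nuclear-encoded mitochondrial respiratory chain, and cholesterol synthesis. Lists were tested with camera of limma at a preset correlation of 0.01, adjusted over the 28 lists of a comparison, and again with the correlation estimated from the residuals. Member counts are given over all genes tested and adjusted over the list alone. The candidates Cbln4, Lgi2 and Fgf13 were chosen by the study's authors on these libraries and are not independent evidence.

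Named genes follow a rule. In every comparison of the P10 subtypes and ages the 3 candidates are given. Up to 8 genes per direction with the largest absolute log2 fold change were added, among genes past the threshold with a mean of at least 5 FPKM on the higher side and no overlap between the libraries of both sides (for the difference in age changes, only the threshold and 5 FPKM in some group). Unnamed models, mitochondrial genes, small RNAs and ribosomal pseudogenes were left out. From each list, the passing members of largest change serve as examples, and markers of sorted or other cell types may be given by their means. Genes named outside the rule are said to be chosen after their values were seen.

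Whole groups were at 0 for some genes that stood at 2 FPKM or more in every library of at least 5 other groups, or that are known to be expressed. There were 91 such genes, 52 of them in SST P5 and 29 in oligodendrocytes, and they stayed in the model. The model was tested on simulated data with 16398 genes, the spread of the real ones and 100 genes changed by each of a pair of sizes. Of the genes changed 4-fold it recovered 96 for SST P10 against the other subtypes, 92 for the PV age comparison and 69 for the difference in age changes. At 2-fold these were 52, 48 and 5. It also called 9, 6 and 8 unchanged genes. A list of 20 genes raised by 0.5 was recovered by camera, with 0 of the other lists called. The simulated genes varied independently, so this cannot show how often camera calls lists of correlated genes. Changed genes and list members were drawn from genes of higher mean level only, so recovery of low genes was not tested.

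Alternatives were a pseudocount of 0.1, no filter, a filter of 5 FPKM, rescaling to TPM, quantile normalization, median-of-ratios scaling, blocks by replicate number or by library number, a variance prior without trend, a fit of the compared groups alone, an estimated correlation for the lists, and leaving out each library in turn. Added after the data were seen were fits without the 91 genes at 0, with both oligodendrocyte columns counted, with chandelier P10 replicate 1 alone for its group, and counts without the genes higher in pyramidal cells or in oligodendrocytes. With replicate 1 alone the chandelier P10 group holds 1 library, assumed to vary like the libraries of the other groups. A call lost there can come from fewer libraries as well as from a smaller difference. Group labels were also permuted. The labels do not state that replicate numbers pair libraries. Across genes, which are not independent replicates, deviations from the group means correlated at 0.41, 0.23 and 0.18 for the 3 same-numbered pairs of chandelier P8 and P10, each over the bound of 0.1. Blocked values are therefore given beside the chandelier age result. SST P10 with PV P10 (0.11, 0.2 and 0.17) and SST P5 with PV P5 (0.18, 0.13 and 0.19) were over it too. The tested comparisons with these groups also held other groups, with at least 1 same-numbered pair below the bound. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.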

Results

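The data are transcript levels, in FPKM, of cell populations sorted from the postnatal mouse cortex. Interneurons that express somatostatin (SST) came from the GIN line at P5 and P10 (postnatal days 5 and 10). Parvalbumin (PV) basket cells came from the G42 line at P5 and P10, and chandelier cells, which contact the axon initial segment of pyramidal cells, from Nkx2-1CreERT2;Ai9 mice at P8 and P10. Control populations were interneurons of the medial ganglionic eminence (MGE) lineage at P0 (Nkx2-1Cre;RCE), pyramidal cells at P12 (Nex-Cre) and oligodendrocytes at P10 (PLP-GFP). Each group held 3 libraries, except the oligodendrocytes, whose 2 near-identical columns were counted as 1. The title and design pose the question of which genes set the inhibitory subtypes apart while their synapses form.

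Each subtype came from its own mouse line, strain and dissected region. SST cells were taken from all layers of the somatosensory cortex, PV cells from the lower layers and chandelier cells from the upper layers of the prefrontal cortex. Differences between subtypes are therefore also differences between lines, strains and regions. The early chandelier libraries are labelled P8 although the design text gives P5 for the early stage, so the chandelier interval is shorter than that of the other subtypes. The first 4 principal components of the 25 libraries held 25.1%, 15.9%, 9.61% and 6.94% of the variance. Summed FPKM ranged from 466208 in interneuron P0 replicate 1 to 633202 in SST P10 replicate 2. Protein-coding mitochondrial transcripts took 1.33% of the sum in pyramidal P12 replicate 1 and 4.29% in chandelier P8 replicate 3, but mt-Co3, mt-Atp6 and mt-Atp8 were listed at 0 in chandelier P8 and PV P10, so these shares are not comparable between groups. Levels below are means ± SD over 3 libraries, with n = 3 unless stated, and fold changes are on the log2(FPKM + 1) scale with the standard error (SE) of the limma model. For gene lists, the camera adjusted p at the preset correlation comes first and that with an estimated correlation second.

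The 3 candidate genes of the study each stood highest in a different P10 subtype. Cbln4 (ENSMUSG00000067578), which encodes a secreted cerebellin that bridges synaptic partners, reached 21.0 ± 3.31 FPKM in SST P10, 0.813 ± 0.197 in PV P10 and 3.73 ± 2.57 in chandelier P10. Lgi2 (ENSMUSG00000039252), a secreted protein of the family that binds ADAM receptors at synapses, stood at 26.2 ± 5.65 FPKM in PV P10, 6.83 ± 3.18 in chandelier P10 and 2.82 ± 1.06 in SST P10. Fgf13 (ENSMUSG00000031137), an intracellular FGF homologue that binds sodium channels and microtubules, had 260 ± 78.7 FPKM in chandelier P10, 71.7 ± 4.86 in PV P10 and 41.3 ± 6.06 in SST P10. The differences from the other two subtypes were 2.97 for Cbln4 (SE 0.26, limma adjusted p = 3.6e-08), 2.35 for Lgi2 (SE 0.29, adjusted p = 1.6e-05) and 2.19 for Fgf13 (SE 0.22, adjusted p = 4.9e-07). All 3 libraries of the named subtype stood above all 6 of the others. In the remaining P10 comparisons Cbln4 was lower in PV cells by a log2 change of -2.43 (adjusted p = 2.3e-06), Lgi2 lower in SST cells (-1.92, adjusted p = 5e-05) and Fgf13 lower in SST cells (-1.69, adjusted p = 8.7e-06), all by limma. Cbln4 and Lgi2 did not pass for chandelier cells (-0.54, adjusted p = 0.15, and -0.43, adjusted p = 0.32), nor did Fgf13 for PV cells (-0.5, adjusted p = 0.19). Without chandelier P10 replicate 1, Cbln4 in chandelier cells (-0.95, adjusted p = 0.0047) and Fgf13 in PV cells (-0.64, adjusted p = 0.041) passed. Since these genes were chosen on these same libraries, the values are not independent evidence.

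**Figure D1:**
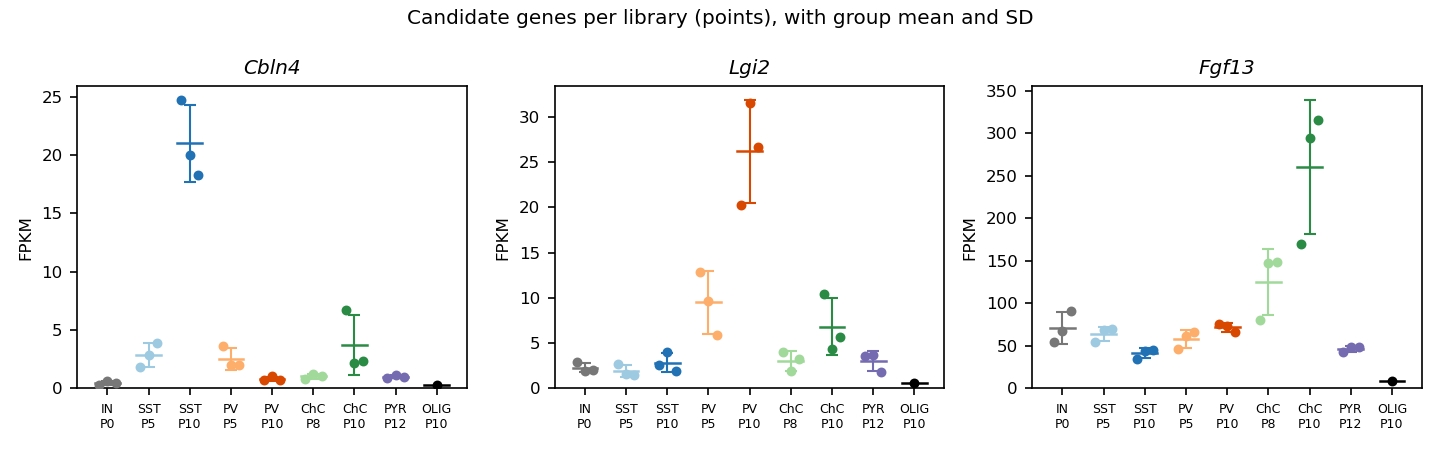
FPKM of Cbln4, Lgi2 and Fgf13 in each library (points) of the 9 groups, with the group mean and SD (horizontal and vertical lines); oligodendrocytes are 1 averaged value. At P10 the means are 21.0 FPKM for Cbln4 in SST cells, 26.2 for Lgi2 in PV cells and 260 for Fgf13 in chandelier cells, where the libraries run from 170 to 316.

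SST cells at P10 were compared with the mean of PV and chandelier cells to find genes that set them apart. Among SST interneuron markers, 6 of 9 were higher and 1 was lower (6 and 1 adjusted over the list alone). Reln, a secreted glycoprotein of the extracellular matrix, was higher by 2.49, Sst itself by 2.18 and the glutamate receptor gene Grm1 by 1.5, while the neuropeptide gene Npy was lower (-2.02). Sst stood at 1900 ± 394 FPKM in SST P10 and at 1950 ± 545 in PV P10, so its difference rested on the 89.4 ± 5.07 of chandelier P10, and it missed the threshold without SST P10 replicate 2 (2.03, limma adjusted p = 0.053). Pyramidal neuron markers were higher for 12 of 15 members and lower for 1 (12 and 1 adjusted over the list alone). They included the vesicular glutamate transporter genes Slc17a6 and Slc17a7. Slc17a6 was at 95.1 to 110 FPKM in the 3 SST P10 libraries against 20.9 ± 2.71 in sorted pyramidal cells, and Slc17a7 at 53.8 ± 13.7 against 63.1 ± 12.9. In the same libraries 12 of 16 MGE interneuron core genes were lower and 1 was higher (12 and 1 adjusted over the list alone), with Erbb4, a neuregulin receptor, at -4.86, Lhx6, a transcription factor of MGE interneurons, at -2.28, and the GABA-synthesizing Gad1 at -2.03. Gad1 stood at 117 ± 33.3 FPKM, against 413 ± 37.2 in PV P10 and 568 ± 214 in chandelier P10.

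The genes of largest change were Nr4a2, a nuclear receptor, with a log2 fold change of 7.51 (SE 0.33, limma adjusted p = 2.1e-12), Lxn, a carboxypeptidase inhibitor (6.16, SE 0.35), the opioid peptide gene Pdyn (5.47, SE 0.44) and the synaptic vesicle gene Synpr (5.46, SE 0.28). Next came the kappa opioid receptor gene Oprk1 (5.36, SE 0.26), the somatostatin receptor gene Sstr2 (5.32, SE 0.36), Slc17a6 (5.24, SE 0.18) and the chemokine gene Cxcl12 (5.12, SE 0.34). Nr4a2 was at 358 to 557 FPKM in the SST P10 libraries and at 486 to 633 in those of SST P5. Lower were Tac1, which encodes substance P (-6.2, SE 0.46, adjusted p = 5.5e-09 by limma), Erbb4 (SE 0.22), Sparc, a matrix protein gene (-4.72, SE 0.54), Cdca7 (-4, SE 0.26), Nxph2, a neurexin ligand (-3.93, SE 0.26), the cortistatin gene Cort (-3.88, SE 0.35) and Id3 (-3.69, SE 0.31). Tuba1c was listed at 0 in SST P10, where the near-identical Tuba1a and Tuba1b were listed at 0 too, so no difference is given. Among other lists, PV basket cell markers were lower for 8 of 11 members and higher for 1 (8 and 1 adjusted over the list alone), and presynaptic vesicle genes were higher for 5 of 21 and lower for 1 (7 and 2), with Sv2b at 4.11. Perineuronal net and matrix genes were lower for 4 of 14 and higher for 1 (4 and 1), with Hapln1 at -3.59. The Hapln1 difference rested on chandelier P10 (29.6, 423 and 403 FPKM), as this gene was at 0.613 to 1.21 FPKM in SST P10 and at 1.49 to 3.66 in PV P10.

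In all, 2944 of 16398 genes passed in this comparison, 1663 higher and 1281 lower in SST cells (limma, Benjamini-Hochberg adjusted). The share of higher genes was 56.5%, and 45.9% after rescaling to TPM, which moved the median of all genes to -0.14. Without the genes higher in pyramidal cells it was 40.8%, with 837 higher and 1212 lower. With camera at the preset correlation, pyramidal markers passed as higher (adjusted p = 5.7e-11, and adjusted p = 0.018 with an estimated correlation) and MGE core genes as lower (1.3e-10, then 0.018). PV markers passed as lower only at the preset correlation (adjusted p = 1.2e-05, and adjusted p = 0.056 with an estimated correlation), as did presynaptic genes as higher (0.0079, then 0.62), perineuronal net genes as lower (0.0079, then 0.46) and oligodendrocyte lineage markers as lower (0.00023, then 0.62). The lineage markers were lowest in chandelier P10 replicate 1, for example Gpr17 at 3.02 FPKM against 525 and 527. Their difference therefore rested mainly on chandelier P10 replicates 2 and 3. SST markers did not pass by camera (adjusted p = 0.071). Above each other subtype singly stood 559 genes, and 279 of them were left without the same pyramidal set, with the same limit.

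PV cells at P10 were compared with the mean of SST and chandelier cells for the same purpose. PV basket cell markers were higher for 7 of 11 members and lower for none (7 adjusted over the list alone). Pvalb, which encodes the calcium buffer parvalbumin, stood at 17.9 ± 4.93 FPKM against 2.42 ± 2.67 in SST P10 and 0.955 ± 0.546 in chandelier P10. Tac1 was higher by 4.35, Cox6a2, a subunit of cytochrome c oxidase, by 3.05, the potassium channel gene Kcnc2 by 2.6 and Syt2, the synaptotagmin of fast-spiking terminals, by 2.57. Potassium and HCN channel genes were higher for 8 of 37 members (12), among them Hcn1 at 1.5. GABA receptor subunits were higher for 6 of 16 (9 higher and 1 lower adjusted over the list alone), among them Gabra4 at 1.52, and neuropeptides for 9 of 16, with 1 lower (10 and 3 adjusted over the list alone). Lower were 6 of 13 cholesterol synthesis genes (8), with Fdps at -1.31 and Ldlr at -1.28. Markers of other cells were lower as well, 6 of 12 of the oligodendrocyte lineage (8 adjusted over the list alone), 4 of 11 of microglia (9) and 4 of 5 red blood cell transcripts (4), while Slc17a7 was higher by 1.12. The oligodendrocyte lineage differences rested mainly on chandelier replicates 2 and 3, as Gpr17 was at 0 to 0.361 FPKM in PV P10 and 0 to 0.417 in SST P10, and Pdgfra at 0 to 0.404 and 0.14 to 0.366. With chandelier P10 replicate 1 alone for its group the calls of Olig1, Olig2, Sox10, Gpr17, Pdgfra and Cspg4 ended. Those of microglial C1qb, P2ry12 and Trem2 ended too. That group then holds 1 library, so these losses do not by themselves show a smaller difference. Without any single P10 library other than chandelier replicate 1, Gpr17 (adjusted p = 0.063 to 0.14), Pdgfra (0.063 to 0.14) and Sox10 (0.067 to 0.13) missed the threshold by limma. Olig1 (adjusted p = 0.059 to 0.1) did so without chandelier replicate 2 or 3 or any PV replicate, Olig2 (0.063 and 0.071) without PV replicates 1 and 3 and Cspg4 (0.075 and 0.066) without PV replicates 2 and 3, by limma. Slc17a7 missed the threshold without PV P10 replicate 1 (0.94, limma adjusted p = 0.13) or 3 (1.02, adjusted p = 0.11). Hcn1 missed it without PV P10 replicate 2 (1.35, adjusted p = 0.056). Neither passed with chandelier P10 replicate 1 alone (1.03 and 1.4). The call of Ldlr ended without PV P10 replicate 2 (-0.84, adjusted p = 0.26) or 3 (-1.33, adjusted p = 0.091), chandelier P10 replicate 2 (-1.29, adjusted p = 0.056) or SST P10 replicate 3 (-1.14, adjusted p = 0.075), each by limma.

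By size of change, the genes higher in PV cells were Rbp4, a retinol carrier (4.76, SE 0.29, limma adjusted p = 7.3e-10), Ostn, a secreted peptide (4.7, SE 0.31), the tyrosine hydroxylase gene Th (4.21, SE 0.49), and the galectin gene Lgals1 (4.1, SE 0.39). They also included Crym, a thyroid hormone binding protein (3.31, SE 0.34), the vesicular zinc transporter gene Slc30a3 (3.2, SE 0.33) and Postn, a matrix protein (3.2, SE 0.35). Lower were Kit, a receptor tyrosine kinase (-4.13, SE 0.35, adjusted p = 1.4e-07 by limma), S100a16 (-3.74, SE 0.6), Id2 (-3.72, SE 0.3), the small heat shock protein gene Cryab (-3.62, SE 0.43), Olfm3 (-3.37, SE 0.45) and Rgs10 (-3.11, SE 0.31). Tpm3-rs7 (3.6), Eif3s6-ps2 (-4.68) and Eif5al3-ps (-4.62) met the rule too, but they are near-identical copies of other genes whose reads they share, and their values are uncertain.

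Of 16398 genes, 1233 passed for PV cells, 660 higher and 573 lower (limma, Benjamini-Hochberg adjusted). The share of higher genes was 53.5%, and 42.9% after rescaling to TPM. Only the PV marker list held with both camera settings (adjusted p = 2.4e-13, and adjusted p = 0.0032 with an estimated correlation). Among the lists that passed at the preset value alone were potassium channels (4.4e-07, and adjusted p = 0.14 with an estimated correlation), GABA receptor subunits (0.0015, then 0.15), and neuropeptides (0.00031, then 0.15). As lower passed cholesterol synthesis (1.2e-06, then 0.14), oligodendrocyte lineage (1.2e-06, then 0.2), microglia (3.7e-07, then 0.18) and red blood cell transcripts (4.2e-05, then 0.14). Above each of the other two subtypes singly stood 176 genes. The count of 1233 became 2104 without chandelier P10 replicate 1, 732 without PV P10 replicate 3, 757 without PV P10 replicate 2 and 738 in a fit of the compared groups alone. With chandelier replicate 1 standing alone for its group it was 790, and the 176 became 111.

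Chandelier cells at P10 were compared with the mean of SST and PV cells. Chandelier cell markers were higher for 4 of 7 members and lower for 1 (4 and 1 adjusted over the list alone). Higher were Pthlh, a secreted peptide, by 3.66, the netrin receptor gene Unc5b by 2.77, the VIP receptor gene Vipr2 by 2.53 and the transcription factor gene Nkx2-1, whose promoter drives the recombinase of this line, by 1.72, with Rasgrp1 at -3.62. MGE core genes were higher for 10 of 16 members and lower for 1 (10 and 1), led by Erbb4 at 2.69. This need not place chandelier cells above PV cells, since SST P10 was low (Erbb4 at 0.00812 of PV P10, median 0.316 over the 16). Satb1 was lower (-2.35). SST markers were lower for 5 of 9 and higher for 2 (5 and 2). Pyramidal markers were lower for 12 of 15 and higher for 1 (12 and 1). Presynaptic vesicle genes were lower for 14 of 21 members (20), for example Syn1 at -1.37 and Snap25 at -1.18. Syn1 missed the threshold without chandelier P10 replicate 2 (-1.08, limma adjusted p = 0.17) or 3 (-1.08, adjusted p = 0.16), without SST P10 replicate 1 (-1.29, adjusted p = 0.055) and without PV P10 replicate 3 (-1.3, adjusted p = 0.05). Potassium and HCN channels were lower for 17 of 37 and higher for 1 (19 and 3), for example Kcnj9 at -3.03. Perineuronal net and matrix genes were higher for 6 of 14 and lower for 1 (6 and 1 adjusted over the list alone), and glutamate receptor subunits lower for 11 of 27 and higher for 3 (11 and 3). The direction turned for the matrix genes Vcan and Tnr with chandelier P10 replicate 1 alone for its group.

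All 12 tested oligodendrocyte lineage markers were higher in the mean of these chandelier libraries (12 adjusted over the list alone), as were 9 of 11 microglia markers (9), 4 of 5 red blood cell transcripts (4) and 7 of 13 cholesterol synthesis genes (10). Mag, Mog, Mobp and Cldn11 missed the threshold without chandelier P10 replicate 2 (limma adjusted p = 0.075, 0.076, 0.2 and 0.067 in that order) and without replicate 3 (adjusted p = 0.065, 0.091, 0.099 and 0.064 by limma), and Mobp also with a pseudocount of 0.1. With replicate 1 alone for the group the direction turned for Mag (-0.24), Mog (-0.09), Mobp (-0.29), Cldn11 (-0.26) and Enpp6 (-0.12), and for microglial Tmem119 (-0.05), Tyrobp (-0.53) and Ctss (-0.21). In that setting Ugt8a (0.54), Gpr17 (1.84), Pdgfra (1.35), Cd9 (1.83) and Neu4 (1.45) kept the direction but did not pass. Gpr17, a receptor of maturing oligodendrocyte precursors, was at 3.02, 525 and 527 FPKM in replicates 1, 2 and 3, and Pdgfra, the receptor that marks the precursors, at 2.12, 180 and 107. Microglial C1qb was at 6.15, 28.4 and 20.6. Hapln1, a link protein of the hyaluronan matrix, varied with them at 29.6, 423 and 403 FPKM, although sorted oligodendrocytes held only 6.13. The named genes higher in chandelier cells were Gpr17 (6.53, SE 0.98, limma adjusted p = 6.9e-05), Hapln1 (6.13, SE 0.58, adjusted p = 2.9e-07) and S100a16 (6.1, SE 0.6). Also higher were the tetraspanin gene Cd9 (5.69, SE 0.82), Pdgfra (5.01, SE 0.77), the sialidase gene Neu4 (5, SE 0.75) and Cdca7 (4.76, SE 0.26). Tuba1c met the rule too, but its near-identical copies Tuba1a and Tuba1b were at 0 and at 75.1 to 150 FPKM in these libraries, and no difference is given. Lower were Nr4a2 (-5.21, SE 0.33), Synpr (-4.95, SE 0.28), Nrn1, a neurite growth gene (-4.74, SE 0.28), the transcription factor gene Neurod6 (-4.65, SE 0.4), Sst (-4.38, SE 0.57, adjusted p = 1.4e-05 by limma), Sv2b (-4.27, SE 0.39), Slc17a7 (-4.17, SE 0.3) and Pdyn (-4.16, SE 0.44). The Nr4a2 difference rested mainly on SST P10, as PV P10 held 2.77 to 6.07 FPKM.

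**Figure D2:**
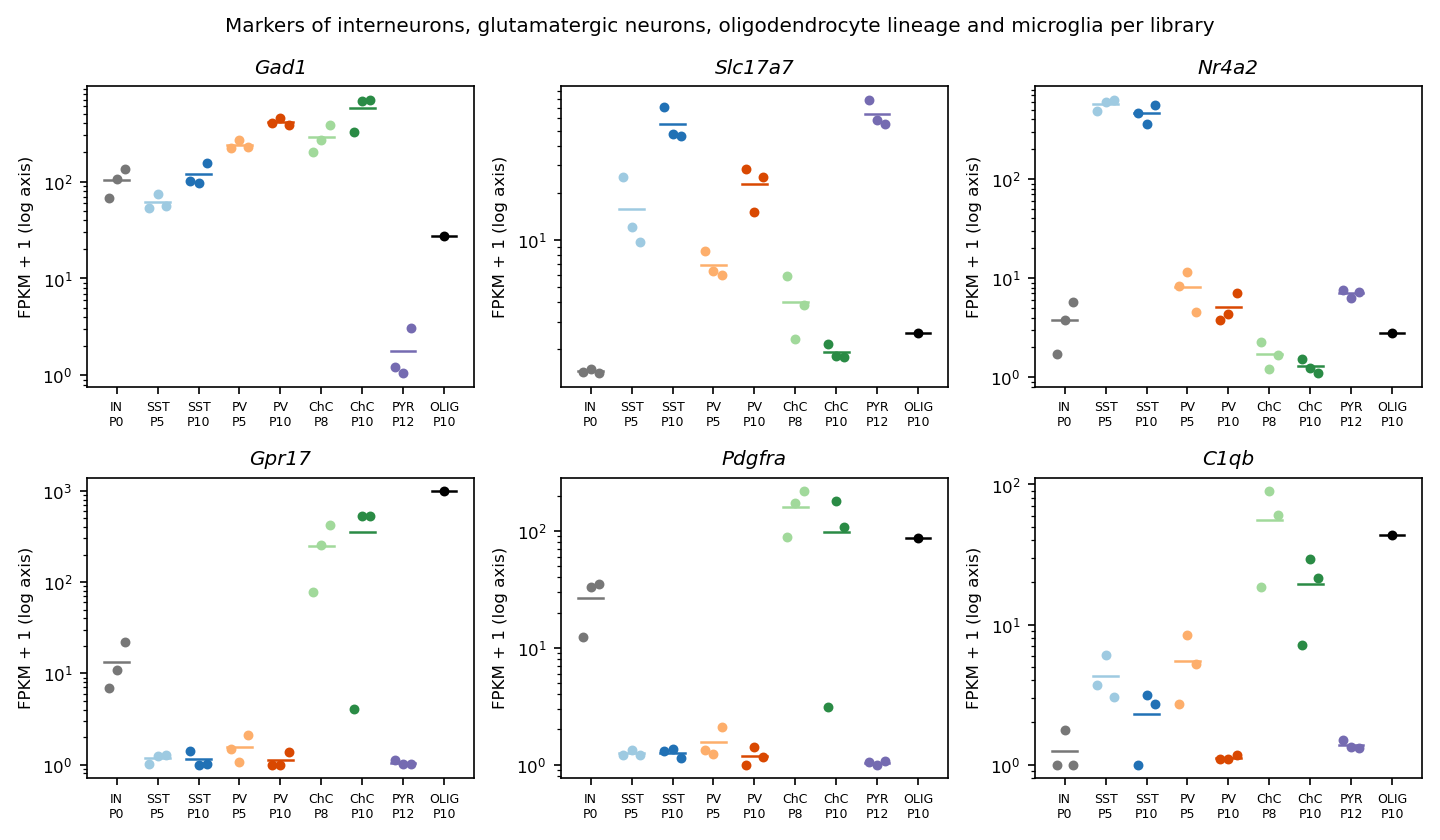
FPKM + 1 (log axis) in each library (points) of the 9 groups, with the group mean as a line. Shown are markers of interneurons (Gad1), glutamatergic neurons (Slc17a7), the oligodendrocyte lineage (Gpr17, Pdgfra) and microglia (C1qb). Nr4a2, shown beside them, is at 5.31 to 6.54 FPKM in pyramidal cells. Slc17a7 averages 53.8 FPKM in SST P10 and 63.1 in pyramidal cells, and Gpr17 is at 3.02 FPKM in chandelier P10 replicate 1 but 525 and 527 in the other two.

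For chandelier cells 3449 of 16398 genes passed, 1606 higher and 1843 lower (limma, Benjamini-Hochberg adjusted). The share of higher genes was 46.6%, and 66.4% after rescaling to TPM, which moved the median of all genes to 0.17. Without the genes higher in oligodendrocytes it was 28%, with 682 higher and 1754 lower. Pyramidal markers were lower with both camera settings (adjusted p = 3.8e-11, and adjusted p = 0.03 with an estimated correlation). Among the lists lost with an estimated correlation were chandelier markers (0.008, and adjusted p = 0.16 with an estimated correlation), MGE core (9.3e-06, then 0.14), and SST markers (0.0088, then 0.18). Also lost were presynaptic genes (3.1e-10, then 0.14), potassium channels (2.6e-05, then 0.17), matrix genes (0.0041, then 0.17), and glutamate receptors (0.0088, then 0.24). Of the markers of other cells, oligodendrocyte markers (6.7e-11, then 0.16), microglia (6.4e-06, then 0.23), and red blood cell transcripts (0.00083, then 0.16) were lost, as was cholesterol synthesis (0.00011, then 0.17). The 3449 became 2169 without replicate 2, 2232 without replicate 3 and 1527 with replicate 1 alone for the group. Above each other subtype stood 512 genes, and 778 after rescaling to TPM. This count was 897 without chandelier replicate 1, 321 without replicate 2 and 324 without replicate 3. In a fit of the compared groups it was 301, and without the same oligodendrocyte set 129, with the same limit.

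SST cells at P10 were compared with SST cells at P5 to ask what changed as they matured. SST markers rose for 3 of 9 members (6 adjusted over the list alone). Sst went from 321 ± 114 to 1900 ± 394 FPKM and Crhbp, which binds corticotropin-releasing hormone, from 1.04 ± 0.502 to 42.6 ± 12.8. Sst missed the threshold without SST P5 replicate 3 (2.3, limma adjusted p = 0.13), SST P10 replicate 1 (2.62, adjusted p = 0.067) or SST P10 replicate 2 (2.45, adjusted p = 0.083). It also did so with a pseudocount of 0.1 (adjusted p = 0.069) and a block on library number (adjusted p = 0.057), by limma. Of the candidates, Cbln4 rose by 2.54 (SE 0.29, limma adjusted p = 1e-05), from 2.85 ± 0.997 to 21.0 ± 3.31 FPKM. Lgi2 (0.36, adjusted p = 0.61) and Fgf13 (-0.63, adjusted p = 0.17) did not pass by limma. Presynaptic vesicle genes rose for 8 of 21 (11), for example Syn2 by 1.4 and Vamp1 by 1.23. Syn2 missed the threshold without SST P5 replicate 3 (1.2, limma adjusted p = 0.1) or SST P10 replicate 2 (1.29, adjusted p = 0.063), and Vamp1 without SST P10 replicate 3 (1.02, adjusted p = 0.061) or SST P5 replicate 1 (1.07, adjusted p = 0.05). Axon initial segment and node genes rose for 3 of 18 (7 higher and 1 lower adjusted over the list alone), among them Kcna1 by 2.37 and Cntnap1 by 2.08, and nuclear mitochondrial respiratory chain genes for 6 of 23 (19 adjusted over the list alone). Immature and migrating neuron genes fell for 5 of 19 (9), among them the microtubule gene Dcx (-2.1) and Tubb2b (-1.64).

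Other lists held changed genes in this comparison as well. Neuropeptides rose for 6 of 16 (7 higher and 1 lower adjusted over the list alone), and MGE core genes for 3 of 16 (4), with Gad2 at 2.09. CGE interneuron markers rose for 3 of 11 (3), where the mean of 0.68 and the test were positive but the median was -0.17. The named genes that rose were Crhbp (4.41, SE 0.36, limma adjusted p = 3.6e-08), Calb2, a calcium-binding protein (4.35, SE 0.41, adjusted p = 4.2e-07), Mgp (3.45, SE 0.39) and the cathepsin gene Ctsk (2.81, SE 0.3). Further ones were Gabrd, a subunit of extrasynaptic GABA receptors (2.77, SE 0.34), Pdyn (2.76, SE 0.51), Myl4 (2.7, SE 0.31) and the carbonic anhydrase gene Car2 (2.65, SE 0.41). Those that fell were St8sia2, which adds polysialic acid to NCAM (-3.05, SE 0.3, adjusted p = 1e-06 by limma), B3gnt5 (-2.67, SE 0.43), Mex3a (-2.58, SE 0.26), and the imprinting regulator Zfp57 (-2.36, SE 0.35). Also lower were Csrp2 (-2.32, SE 0.25), Casp3 (-2.18, SE 0.29), Glipr2 (-2.15, SE 0.36) and Dcx (SE 0.25). With a pseudocount of 0.1, Pdyn (2.81, limma adjusted p = 0.085) and Glipr2 (-2.75, adjusted p = 0.097) did not pass. Slc17a7 rose by 1.9 in the same libraries, and Slc17a6 stood at 96.7 to 124 FPKM at P5 and 95.1 to 110 at P10.

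For the SST age comparison 919 of 16398 genes passed, 585 higher and 334 lower at P10 (limma, Benjamini-Hochberg adjusted), and the 63.7% of higher genes became 39.8% after rescaling to TPM, which moved the median of all genes to -0.17. At the preset correlation camera called, among others, SST markers (adjusted p = 2.8e-05), presynaptic genes (2.4e-07), axon initial segment genes (0.0084), mitochondrial genes (1.5e-10), neuropeptides (0.0015), MGE core (4.3e-05) and CGE markers (0.027) as higher and immature genes (7.4e-06) as lower. No list held, and these had adjusted p = 0.091, 0.14, 0.12, 0.12, 0.23, 0.12, 0.34 and 0.065 with an estimated correlation. The count of 919 became 401 without SST P5 replicate 3, 510 without SST P10 replicate 1, 554 without SST P10 replicate 2 and 611 in a fit of the compared groups alone. Without genes listed at 0 in a whole group, 868 of the 919 were left.

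PV cells at P10 were compared with PV cells at P5. PV basket cell markers rose for 8 of 11 members (10 adjusted over the list alone). Pvalb went from 0.109 ± 0.161 to 17.9 ± 4.93 FPKM, Syt2 from 0.608 ± 0.219 to 10.9 ± 2.68 and Cox6a2 from 3.37 ± 1.35 to 53.2 ± 15.4. Lgi2 rose by 1.41 (SE 0.33, limma adjusted p = 0.012), from 9.49 ± 3.49 to 26.2 ± 5.65 FPKM, but it no longer passed without PV P10 replicate 2 (adjusted p = 0.068) or PV P5 replicate 3 (adjusted p = 0.083). Cbln4 (-0.93, adjusted p = 0.06) and Fgf13 (0.31, adjusted p = 0.53) did not pass by limma, although Cbln4 passed with a pseudocount of 0.1 (adjusted p = 0.04) and a block on library number (adjusted p = 0.029). Nuclear mitochondrial respiratory chain genes rose for 12 of 23 (22), led by the cytochrome c gene Cycs at 1.45. Axon initial segment and node genes rose for 7 of 18 (8), among them the sodium channel subunits Scn2b (2.32) and Scn1b (2.11). So did potassium and HCN channels for 11 of 37 (15), presynaptic vesicle genes for 9 of 21 (12) and GABA receptor subunits for 5 of 16 (6 higher and 1 lower adjusted over the list alone). Immature and migrating neuron genes fell for 10 of 19 (15), among them the semaphorin receptors Nrp1 (-2.12) and Nrp2 (-2.05) and Dcx (-1.88). Axon guidance genes fell for 6 of 41 and rose for 1 (7 and 1 adjusted over the list alone), and cholesterol synthesis genes fell for 3 of 13 (7).

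Genes of largest rise were Pvalb (4.07, SE 0.39, limma adjusted p = 2.8e-06), Cox6a2 (3.64, SE 0.41), Akr1c18, a steroid dehydrogenase (3.53, SE 0.41), Myl4 (3.22, SE 0.31), Tcap (3.07, SE 0.4), Syt2 (2.87, SE 0.23), Cthrc1 (2.78, SE 0.61) and Nrn1 (2.76, SE 0.32). Genes of largest fall were the neurotensin gene Nts (-3.99, SE 0.72, adjusted p = 0.0018 by limma), the transcription factor genes Isl1 (-3.53, SE 0.66), Zic4 (-3.34, SE 0.5) and Foxp2 (-2.99, SE 0.46), Amelx (-3.13, SE 0.35) and Fgf15 (-3.1, SE 0.36). Gnrh1, at 8.29, 16.9 and 4.35 FPKM in the PV P5 libraries, and Mgst1, at 7.02, 10.2 and 3.66, were listed at 0 in all of PV P10. Beside these, 4 of 5 red blood cell transcripts fell (4 adjusted over the list alone) and so did 1 of 11 microglia markers, C1qb (2 adjusted over the list alone). C1qb missed the threshold after quantile normalization (-1.92, limma adjusted p = 0.051). It also did so without PV P10 replicates 1, 2 and 3 (adjusted p = 0.061, 0.08 and 0.059) and without PV P5 replicates 2 and 3 (adjusted p = 0.11 and 0.081), in turn and by limma.

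The PV age comparison called 1193 of 16398 genes, 697 higher and 496 lower at P10 (limma, Benjamini-Hochberg adjusted), and the 58.4% of higher genes became 32.8% after rescaling to TPM, which moved the median of all genes to -0.22. Held with both camera settings were PV markers (adjusted p = 1.3e-14, and adjusted p = 0.0015 with an estimated correlation), immature genes as lower (2.7e-11, then 0.0015), axon initial segment genes (5.5e-05, then 0.012) and mitochondrial genes (2.2e-15, then 0.037). Among lists called at the preset value alone were potassium channels (1.9e-08, and adjusted p = 0.082 with an estimated correlation), presynaptic genes (5.9e-11, then 0.059), GABA receptors (0.00095, then 0.12), and, as lower, axon guidance (0.0058, then 0.29), cholesterol synthesis (5.9e-05, then 0.15), red blood cell transcripts (0.00089, then 0.12) and microglia (0.0014, then 0.44). Without PV P10 replicate 2 the count was 578, without PV P5 replicate 3 it was 610 and without PV P5 replicate 1 it was 750.

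Chandelier cells at P10 were compared with chandelier cells at P8. Fgf13 rose by 1.05 (SE 0.25, limma adjusted p = 0.047), from 125 ± 38.8 to 260 ± 78.7 FPKM, whereas Cbln4 (1.1, adjusted p = 0.074) and Lgi2 (0.92, adjusted p = 0.21) did not pass by limma. Fgf13 missed the threshold without chandelier P8 replicate 1 (0.76, adjusted p = 0.13) or 2 (1.19, adjusted p = 0.072) and without chandelier P10 replicate 2 (0.94, adjusted p = 0.094) or 3 (0.89, adjusted p = 0.16). Without chandelier P10 replicate 2 Cbln4 passed (1.32, adjusted p = 0.039). With all libraries, the 3 candidates passed when adjusted over the list alone, which is not independent evidence. Cell cycle genes fell for 6 of 15 members (12 adjusted over the list alone), among them the cyclin gene Ccnb1 (-2.55) and the topoisomerase gene Top2a (-2.09), which went from 20.3 ± 6.74 to 4.26 ± 2.67 FPKM. PV basket cell markers rose for 1 of 11 (5), Kcnc2 by 1.32, and axon initial segment genes for 1 of 18 (2), Fgf13 itself. Pyramidal markers fell for 2 of 15 (9), with Neurod6 at -2.56. None of the 12 oligodendrocyte lineage, 10 astrocyte, 11 microglia or 5 red blood cell members passed over all genes, while 2, 2, 4 and 2 were lower when adjusted over the list alone. The precursor gene Pdgfra was at 88.3, 174 and 218 FPKM in chandelier P8 replicates 1, 2 and 3 and at 2.12, 180 and 107 in those of P10. Gpr17 was at 77.3, 253 and 417 FPKM at P8 and at 3.02, 525 and 527 at P10. The named genes that rose were Cort (2.49, SE 0.4, adjusted p = 0.0041 by limma), the cholesterol hydroxylase gene Ch25h (2.25, SE 0.54), Gabrd (2.13, SE 0.34) and Nek7 (1.83, SE 0.29). Smaller rises were those of Adamts15, a matrix protease (1.72, SE 0.24), Akr1c18 (1.71, SE 0.41), the calcium-binding protein gene Scgn (1.62, SE 0.33) and the lipase gene Lpl (1.58, SE 0.37). Those that fell were Pnlip (-2.95, SE 0.65), Crym (-2.63, SE 0.39), Neurod6 (SE 0.46), the mitotic kinase gene Pbk (-2.55, SE 0.57), Ccnb1 (SE 0.49), the chemokine gene Ccl4 (-2.38, SE 0.29), Zic4 (-2.33, SE 0.5) and S100a10 (-2.33, SE 0.54). Several of these calls ended without a single library, here given with the highest limma adjusted p. Without chandelier P10 replicate 1 these were Akr1c18 (adjusted p = 0.21), Lpl (0.2), S100a10 (0.17), Pbk (0.16, as without P8 replicate 2) and Neurod6 (0.052). Without chandelier P8 replicate 2 they were Pnlip (adjusted p = 0.12), Ch25h (0.1), Ccnb1 (0.082) and Kcnc2 (0.072). Without chandelier P8 replicate 1 it was Zic4 (adjusted p = 0.08), and without P8 replicate 3 Scgn (0.076). Cort, Gabrd, Nek7, Adamts15, Crym, Ccl4 and Top2a passed without each library in turn. With a pseudocount of 0.1 Adamts15 (limma adjusted p = 0.06), Ccl4 (0.072) and Top2a (0.066) did not pass, nor did Top2a with a block on library number (0.058).

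Only 177 of 16398 genes passed for chandelier age, 65 higher and 112 lower (limma, Benjamini-Hochberg adjusted), and the 36.7% of higher genes became 49.7% after quantile normalization. The direction turned without chandelier P10 replicate 1, with 50 higher and 29 lower genes (63.3% higher). It was nearly even with the filter at 5 FPKM (43 and 40) and without the genes that were higher in oligodendrocytes (60 and 58). With the replicate number as a block, 359 genes passed, 154 higher and 205 lower. Chandelier cell markers as higher and CGE markers as lower passed under the block at the preset correlation (adjusted p = 0.042 for each, and 0.054 without the block). Camera held with both settings for the candidates (adjusted p = 6.5e-05, and adjusted p = 0.015 with an estimated correlation), PV markers (1.9e-07, then 0.015), axon initial segment genes (5e-05, then 0.015) and cell cycle genes as lower (4.7e-17, then 0.015). Among lists lower at the preset value alone were pyramidal (4.5e-06, and adjusted p = 0.076 with an estimated correlation), astrocyte (3.4e-05, then 0.18), microglia (7.3e-06, then 0.21), endothelial and mural (0.033, then 0.25) and red blood cell transcripts (0.003, then 0.17). The count of 177 moved with single settings and was 61 with a pseudocount of 0.1, 83 with the filter at 5 FPKM, 36 with a block on library number and 13 in a fit of the compared groups alone. It was 53 without chandelier P8 replicate 2, and 79, 283 and 115 without chandelier P10 replicates 1, 2 and 3.

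**Figure D3:**
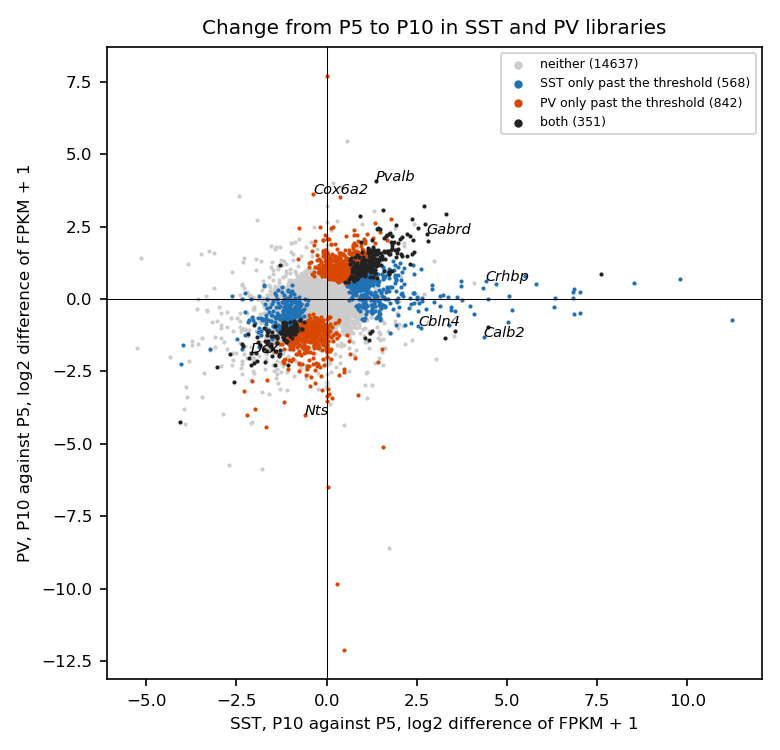
Log2 change of FPKM + 1 from P5 to P10 in SST libraries (horizontal axis) against that in PV libraries (vertical axis) for each of 16398 tested genes (points), coloured by the limma threshold passed. Of these genes 568 passed for SST only, 842 for PV only and 351 for both, and Pvalb and Cox6a2 lie high on the PV axis while Calb2 and Crhbp lie far along the SST axis.

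The age changes of SST and PV cells were then set against each other, as shown in the plot of both changes, first for what they shared. Across the 16398 genes, which are not independent replicates, the log2 changes had a Pearson r of 0.439. Both comparisons called 351 genes, of which 97.7% moved the same way. There were 231 genes higher at P10 in both where 24.9 would be shared by independent choices, and 112 lower in both against 10.1. Myl4 and Gabrd rose and Dcx and Tubb2b fell in both subtypes. The test of the difference itself, the PV change minus the SST change, called 131 genes, 25 with a more positive change in PV cells and 106 with a more positive change in SST cells, 19.1% in the first direction (limma, Benjamini-Hochberg adjusted). PV markers leaned to the PV side for 4 of 11 members (6 adjusted over the list alone), Cox6a2 by 4.02 (SE 0.57), Pvalb by 2.7 (SE 0.55), Kcnab3 by 2.26 (SE 0.45) and Syt2 by 1.96 (SE 0.33). On the SST side stood Calb2 (-5.66, SE 0.58), Crhbp (-3.8, SE 0.5) and Cbln4 (-3.47, SE 0.42, limma adjusted p = 2.4e-05), while Lgi2 (1.05, adjusted p = 0.66) and Fgf13 (0.94, adjusted p = 0.48) did not pass. Camera held for PV markers (adjusted p = 2.6e-10, and adjusted p = 0.011 with an estimated correlation). Of the 131 genes, 81 were left without those listed at 0 in a whole group, and 51 passed when such genes were left out of the fit. Of the 51 genes, 15 were more positive in PV cells and 36 in SST cells, 29.4% in the first direction. Pvalb missed the threshold without SST P5 replicate 2 (2.6, limma adjusted p = 0.053) or SST P10 replicate 1 (2.65, adjusted p = 0.052), and Kcnab3 without SST P5 replicate 2 (2.13, adjusted p = 0.05). With a pseudocount of 0.1 neither Pvalb (adjusted p = 0.45) nor Syt2 (adjusted p = 0.5) passed.

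The mean of SST and PV cells at P5 was compared with the MGE lineage interneurons at P0, the earlier step in age. The P0 cells came from the Nkx2-1Cre;RCE line and the P5 cells from the GIN and G42 lines. Age can therefore not be told apart from the line and the cells sorted. GABA receptor subunits were higher at P5 for 13 of 16 members and lower for 1 (14 and 1 adjusted over the list alone), among them Gabra1 by 2.65 and Gabra4 by 1.9. Presynaptic vesicle genes were higher for 11 of 21 (15), with Syt1 at 1.79. Synaptic adhesion genes and organizers were higher for 14 of 50 and lower for 4 (17 and 4), with Lrrtm3 at 1.73 and Nlgn1 at 1.43. Higher also were protocadherins and cadherins for 9 of 25 (9 higher and 1 lower adjusted over the list alone), with Cdh6 at 2.16, and cholesterol synthesis genes for 10 of 13 (12), with Sqle at 1.59. Potassium and HCN channels were higher for 13 of 37 and lower for 3 (14 and 4 adjusted over the list alone), and axon initial segment genes higher for 7 of 18 (8). MGE core genes were lower for 12 of 16 (12), among them Lhx6 (-2.62), Dlx1 (-2.56) and Arx (-2.47). Oligodendrocyte lineage markers were lower for 6 of 12 (6), with Pdgfra at 25.9 ± 12.7 FPKM in P0 cells. Cell cycle genes were lower for 3 of 15 (3), and pyramidal markers higher for 8 of 15 and lower for 1 (8 and 1).

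Nrgn, a calmodulin-binding protein abundant in pyramidal cells, led the genes higher at P5 (5.28, SE 0.35, limma adjusted p = 1.4e-09), followed by Cryab (4.34, SE 0.43), Sv2b (3.91, SE 0.39) and the tubulin gene Tuba4a (3.82, SE 0.25). After them came the potassium channel gene Kcnv1 (3.63, SE 0.3), the neurofilament gene Nefl (3.59, SE 0.28), Synpr (3.58, SE 0.28) and the G protein gene Gnb4 (3.52, SE 0.24). Gnb4 stood at 958 to 1120 FPKM in SST P5 but at 39.8 to 55.9 in PV P5, and Nrgn at 673 ± 194 and 112 ± 26.6. Genes lower at P5 were Pdgfra (-4.15, SE 0.77, adjusted p = 0.00048 by limma), Id3 (-3.49, SE 0.31), Cbfa2t3 (-3.48, SE 0.26), Olig1 (-3.41, SE 0.46) and Wnt7a (-3.33, SE 0.24). Further down stood the midkine gene Mdk (-3.31, SE 0.32), Gpr17 (-3.17, SE 0.98) and Fabp7, a fatty acid binding protein of radial glia (-3.16, SE 0.74). Gpr17 missed the threshold without interneuron P0 replicate 2 (-3.24, limma adjusted p = 0.066) or 3 (-2.72, adjusted p = 0.098). In all 3546 of 16398 genes passed, 2119 higher and 1427 lower (limma, Benjamini-Hochberg adjusted). MGE core genes were lower with both camera settings (adjusted p = 1.3e-12, and adjusted p = 0.015 with an estimated correlation). Calls at the preset value alone included GABA receptors (1.3e-06, and adjusted p = 0.067 with an estimated correlation), presynaptic genes (1.6e-08, then 0.1), synaptic adhesion (0.018, then 0.22) and cadherins (0.0056, then 0.1). They also included cholesterol synthesis (1.3e-06, then 0.1), potassium channels (0.00041, then 0.27), axon initial segment genes (0.0056, then 0.1), oligodendrocyte lineage (0.0015, then 0.44), cell cycle (0.002, then 0.4) and pyramidal markers (0.0015, then 0.22).

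The mean of the 3 interneuron subtypes at P10 was compared with pyramidal cells at P12 as a check of the sorted types. MGE core genes were higher in interneurons for 16 of 16 members (16 adjusted over the list alone), with Gad1 at 7.55 and the GABA transporter gene Slc6a1 at 6.78. SST markers were higher for 6 of 9 (7 adjusted over the list alone), PV markers higher for 10 of 11 and lower for 1 (10 and 1), and neuropeptides higher for 8 of 16 and lower for 3 (9 and 3). Pyramidal markers were lower for 11 of 15 and higher for 1 (11 and 1 adjusted over the list alone), with the upper-layer gene Cux2 at 0.9, Slc17a7 at -2.27 and Slc17a6 at -1.22. These values average the 3 subtypes. SST P10 by itself held Slc17a6 at 500% of its pyramidal level and Slc17a7 at 85.3%. The lower means of both genes therefore rested mainly on PV and chandelier cells, and for Slc17a6 the SST cells went the other way. Cux2 missed the threshold without pyramidal P12 replicate 2 (0.86, limma adjusted p = 0.12) or 3 (0.72, adjusted p = 0.19), without SST P10 replicate 1 (0.82, adjusted p = 0.053) and without PV P10 replicate 1 (0.85, adjusted p = 0.05). Immediate early genes were lower for 6 of 16 and higher for 1 (7 and 1), among them Egr1 (-2.01). GABA receptor subunits were lower for 6 of 16 and higher for 1 (7 and 2), and synaptic adhesion genes lower for 15 of 50 and higher for 6 (18 and 6). Of the sex-linked genes Xist was higher by 2.72, since it was at 0.0357 ± 0.0111 FPKM in pyramidal cells, and the male-specific Ddx3y stood at 21.7 ± 1.74 FPKM there.

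By size, higher in interneurons were Gad1 (SE 0.3, limma adjusted p = 2.3e-13), Slc6a1 (SE 0.2), Sst (6.68, SE 0.54), Lhx6 (5.73, SE 0.17), Gad2 (5.42, SE 0.25), Npy (5.27, SE 0.23), Dlx1 (4.96, SE 0.21) and Nxph1 (4.92, SE 0.22). Higher in pyramidal cells were Crym (-4.66, SE 0.32, adjusted p = 2.2e-09 by limma), the thyrotropin-releasing hormone gene Trh (-3.89, SE 0.43), Nrn1 (-3.66, SE 0.26) and Atp6ap1l (-3.6, SE 0.5). Next were the gastrin-releasing peptide gene Grp (-3.46, SE 0.38), Ldb2 (-3.43, SE 0.5), the cholecystokinin receptor gene Cckbr (-3.26, SE 0.3) and Rprm (-3.25, SE 0.42). A total of 2745 of 16398 genes passed, 1160 higher and 1585 lower in interneurons (limma, Benjamini-Hochberg adjusted). Camera held with both settings for MGE core (adjusted p = 4.4e-38, and adjusted p = 3.3e-05 with an estimated correlation), SST markers (4.3e-11, then 0.0032), PV markers (7.1e-11, then 0.0036), pyramidal markers as lower (1.2e-08, then 0.021) and the candidates, all 3 higher (0.0018, then 0.017), which is not independent evidence. At the preset value alone it held, among others, for neuropeptides (0.00018, and adjusted p = 0.16 with an estimated correlation), immediate early genes (0.025, then 0.29), GABA receptors (0.0018, then 0.18) and synaptic adhesion (0.046, then 0.29). The count of 2745 became 1724 without pyramidal replicate 1 and 1742 without pyramidal replicate 2.

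Against oligodendrocytes, of which there was 1 averaged library, the interneuron subtypes at P10 differed in the most genes. All 12 tested oligodendrocyte lineage markers were lower in interneurons (12 adjusted over the list alone), as were 13 of 13 cholesterol synthesis genes (13), 9 of 10 astrocyte markers (9), 9 of 11 microglia markers (9) and 12 of 15 cell cycle genes (12). Higher were 19 of 21 presynaptic vesicle genes (21), for example Snap25 at 3.52, 11 of 16 GABA receptor subunits (13), and 15 of 16 MGE core genes (15). Channels and receptors followed with 24 of 37 potassium and HCN channels with 1 lower (26 and 1) and 13 of 27 glutamate receptor subunits with 3 lower (17 and 3). Axon initial segment genes were higher for 12 of 18 with 3 lower (13 and 3), where the lower ones included Nfasc (-4.63). Gad1 was at 26.2 FPKM and C1qb at 42.4 in the oligodendrocyte library. The genes higher by size were Lhx6 (5.25, SE 0.27, limma adjusted p = 4.7e-11), Syt1 (4.53, SE 0.26), Sst (4.52, SE 0.85), Ccdc136 (4.38, SE 0.56), Mef2c (4.18, SE 0.26), Vsnl1 (4.16, SE 0.33) and Stmn2 (4.16, SE 0.25). Eif2s3y (4.48, SE 1.11) is Y-linked, and Ddx3y, also Y-linked, was at 0.202 FPKM in oligodendrocytes, so this difference goes with the sex of the animals. Of the 5 sex-linked genes 4 were higher in interneurons (4 adjusted over the list alone). Lower were the myelin genes Mag (-10.6, SE 0.98, adjusted p = 1e-07 by limma), Mobp (-10.34, SE 0.7), Cldn11 (-9.91, SE 1.17) and Mog (-9.76, SE 0.83), and Ugt8a (-9.12, SE 1.16), Trf (-8.72, SE 0.52), Tsc22d4 (-8.37, SE 0.78) and Enpp6 (-8.04, SE 1.3). The myelin genes Plp1 and Mbp were listed at 0 in oligodendrocytes and were not compared.

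In that comparison 5321 of 16398 genes passed, 2375 higher and 2946 lower in interneurons (limma, Benjamini-Hochberg adjusted), and 7993 when both oligodendrocyte columns were counted. The share of higher genes was 44.6%. It became 51.4% after quantile normalization (2579 higher and 2437 lower), which moved the median of all genes to 0.11, and 50.1% after rescaling to TPM (2532 and 2522). The single oligodendrocyte library was assumed to vary like the libraries of the other groups. Holding with both camera settings were, among others, presynaptic genes (adjusted p = 1e-13, and adjusted p = 0.017 with an estimated correlation), GABA receptors (6.5e-08, then 0.014), MGE core (9.9e-10, then 0.014), potassium channels (2.8e-09, then 0.036), glutamate receptors (1e-05, then 0.041), axon initial segment genes (8e-05, then 0.014) and cholesterol synthesis as lower (3e-08, then 0.036). Oligodendrocyte markers (1.4e-10, and adjusted p = 0.079 with an estimated correlation), astrocyte markers (3.7e-05, then 0.14), microglia (3.7e-05, then 0.21) and cell cycle genes (7.8e-06, then 0.12) were called at the preset value alone. Across all 10 comparisons and 28 lists, 133 list tests were called at the preset correlation and 30 with an estimated one, as the map of list means shows.

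**Figure D4:**
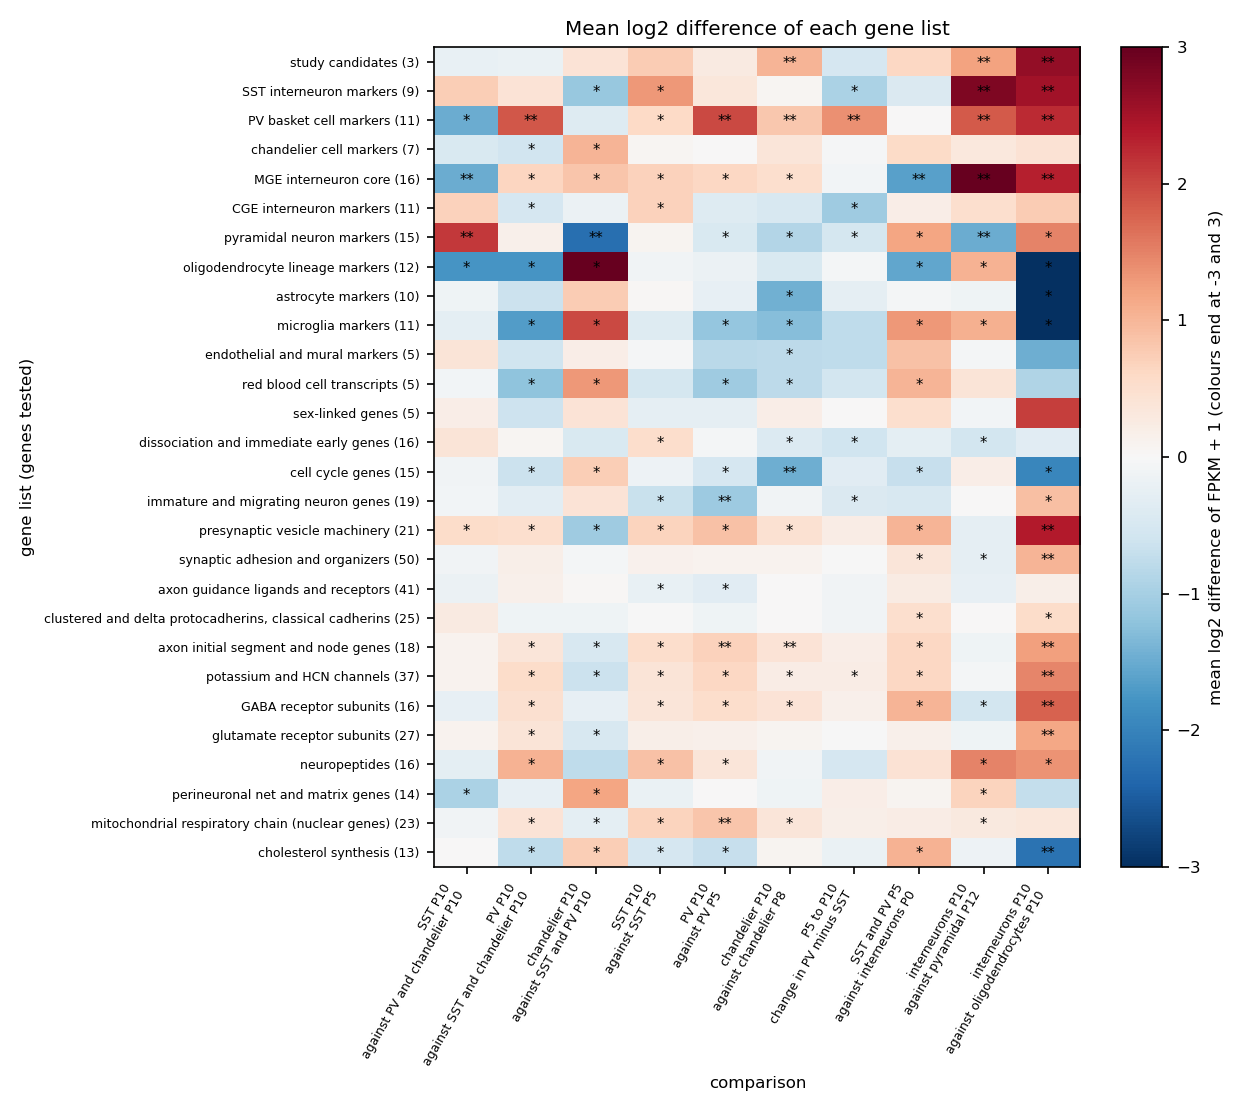
Mean log2 difference of FPKM + 1 (colour, ending at -3 and 3) of the tested members of each of 28 gene lists (vertical axis, number of genes in brackets) in each of 10 comparisons (horizontal axis). One star marks lists called by camera at the preset correlation and a pair of stars those also called with an estimated correlation, 133 and 30 in all.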

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

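The tests of explanations in this part and the relabelling without the shared age change were chosen after the results were seen, and the other relabelling was planned.

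The P5 to P10 change was tested for a difference between PV and SST cells with an interaction term, and each result named here passed that test of difference. In all 131 genes differed (limma, Benjamini-Hochberg adjusted), and 51 when genes listed at 0 in a whole group were left out, on the log2(FPKM + 1) scale as the PV change minus the SST change. More positive in PV cells were Cox6a2 (4.02), Akr1c18 (3.15), Pvalb (2.7), Kcnab3 (2.26), Wls (2.19), Pttg1 (2.09), Prss23 (2) and Syt2 (1.96). More positive in SST cells were Calb2 (-5.66), Crhbp (-3.8), Mgp (-3.72), Cplx3 (-3.62), Sema5b (-3.6), Cbln4 (-3.47), Zic4 (-3.34) and Gnrh1 (-3.34), where Gnrh1 was listed at 0 in PV P10. With a pseudocount of 0.1 Akr1c18, Pvalb, Prss23, Syt2, Mgp and Zic4 did not pass (limma adjusted p = 0.08, 0.45, 0.2, 0.5, 0.091 and 0.077). Wls, Prss23, Sema5b and Zic4 did not pass without single libraries of either subtype, with adjusted p up to 0.068 (Wls, without SST P5 replicate 3), 0.15 (Prss23, SST P10 replicate 1), 0.08 (Sema5b, PV P5 replicate 1) and 0.069 (Zic4, PV P10 replicate 3 or PV P5 replicate 2) by limma. Pvalb and Kcnab3 did not pass without SST P5 replicate 2 (limma adjusted p = 0.053 and 0.05), nor Pvalb without SST P10 replicate 1 (adjusted p = 0.052). Calb2 rose in SST cells, from 8.38 ± 6.1 to 170 ± 51.2 FPKM, while it went from 80.1 ± 29.1 to 31.4 ± 10.8 in PV cells. Of 100 relabellings of ages within each subtype 2, the real one included, called as many genes, with 132 in the real one and 299 in the highest other. That relabelling also removes the age changes that both subtypes share, so it says nothing of a difference between them, and the 299 kept the PV ages and mixed those of SST cells. With the mean age change of both subtypes, estimated from the same libraries, taken off first, the real labelling called 131 and the highest other of the same 100 called 7 (1 of 100). These refits kept the genes listed at 0 in a whole group and were not repeated without them. Chance is therefore not excluded for the 51 genes that differed when such genes were left out.

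Camera called 7 lists in this test of difference at the preset correlation. PV basket cell markers were higher (adjusted p = 2.6e-10, and adjusted p = 0.011 with an estimated correlation). Potassium and HCN channels were higher at the preset value alone (0.035, then 0.7 with an estimated correlation). Lower at the preset value alone were SST markers (0.0055, then 0.3), CGE markers (0.0011, then 0.3), pyramidal markers (0.011, then 0.47), immediate early genes (0.005, then 0.3) and immature neuron genes (0.039, then 0.43), the second value again with an estimated correlation.

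Oligodendrocyte lineage transcripts in chandelier libraries were the first pattern weighed. Cells like the sorted oligodendrocytes are argued against as the only source, since the share of the oligodendrocyte level ran from 0.197% for Mobp to 113% for Pdgfra among 12 lineage markers, a ratio of 574. A varying number of other labelled or glial cells may be the source, as 12 of 12 markers were lowest in the same library, chandelier P10 replicate 1, with Gpr17 at 3.02 FPKM against 525 and 527. Of the myelin genes, Mag and Mog stood at 0.402% and 0.43% of the oligodendrocyte level, while Plp1 (622 and 945 FPKM in replicates 2 and 3) and Mbp (423 and 494) were high there but listed at 0 in oligodendrocytes, so they have no share. The cell sort on the reporter should remove unlabelled cells, but microglia markers and red blood cell transcripts were higher in chandelier P10 too. Line, strain and layers are shared by these replicates and stay open only against other subtypes. Replicate 1 alone has a library number of another series, which stays open.

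Pyramidal neuron transcripts in SST libraries were the second pattern. Of the 60 genes marking the pyramidal libraries, 60% stood in SST P10 at 0.5 times the Slc17a7 share or more. That lies on the bound set for cells like the sorted pyramidal cells and cannot decide. A first run with small RNAs and unnamed gene models gave 56.8% of 74 genes. Shares ran from 3.49% (Crym) to 500% (Slc17a6), with Slc17a7 at 85.3%, a median of 47.2%, 7 genes under 10% and 10 over 100%. This spread argues against such cells as their only source. Glutamatergic cells of another kind could lower the MGE genes, whose median ratio of SST P10 to PV P10 was 0.316 over 16 genes, but the brain region and mouse line differ as well, and this stays open.

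Whole groups listed at 0 were the third pattern, with 91 genes in at least 1 group and 52 of them in SST P5. Failed estimates at a locus may be the source, as 49 of 50 placed genes lay within 3 genes of another, against at most 6 in 1000 random draws, and 46 were on chromosome 8. A deletion in the mouse strain of the SST line is argued against, since only 4 of 52 were at 0 in SST P10 too. Cox4i1, for example, was listed at 0 in SST P5 and at 901, 950 and 809 FPKM in SST P10.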

How the results depend on the processing

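The settings chosen after the data were seen were leaving out genes listed at 0 in a whole group, counting both oligodendrocyte columns, chandelier P10 replicate 1 alone, and leaving out genes high in pyramidal cells or in oligodendrocytes. Where no cause is given, the cause was not tested. Fitting only the compared groups gave 738 genes for PV P10, 611 for SST age and 13 for chandelier age. It gave 301 above both for chandelier cells. PV age, losing as many libraries, kept 1122. Replicate pairs with chandelier replicate 1 varied most (log2 ratio SD 0.675 to 0.707), so the variance pooled over groups may understate their spread. For chandelier age, a pseudocount of 0.1 gave 61, the filter at 5 FPKM 83, a block on library number 36 and both oligodendrocyte columns 278. Both columns gave 7993 against oligodendrocytes. Chandelier P10 replicate 1 alone gave 790 for PV P10, 1527 for chandelier P10, 1416 for chandelier age, and 111 (PV) and 179 (chandelier) above both other subtypes. It also reversed 14 named genes of chandelier P10: Mag (-0.24), Mog (-0.09), Mobp (-0.29), Cldn11 (-0.26), Enpp6 (-0.12), Atp1a2 (-0.5), Tmem119 (-0.05), Tyrobp (-0.53), Ctss (-0.21), Cxcr7 (-0.1), Sema3d (-0.38), Cacng3 (0.13), Vcan (-0.27) and Tnr (-0.37). TPM gave 778 above both for chandelier cells. Without genes listed at 0, the interaction called 51. Without 1956 pyramidal-high genes 279 were above both in SST cells, and without 3150 oligodendrocyte-high genes 129 in chandelier cells. List calls fell from 133 to 30 with an estimated correlation.

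A block on replicate number, which the labels do not state to be a pairing, gave 1449 genes for SST age, 1808 for PV age, 359 for chandelier age, 3632, 1807 and 4430 for SST, PV and chandelier P10, 158 for the interaction, 4472 for P5 against P0, 3468 against pyramidal cells, and 587, 204 and 589 above both. Residuals of libraries with the same number had a median r of 0.115 in 84 pairs, against -0.05 in 168 others, and 22 of 24 libraries were closest to their own number. In chandelier age the block changed no call of a named gene, and among lists only those of chandelier cell and CGE markers. Among named genes elsewhere it let Fgf13 pass for SST age (-0.63, adjusted p = 0.028 by limma) and for PV P10 (-0.5, adjusted p = 0.036), neither of which passed without it, and it ended the call of none.

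Leaving out single libraries gave 2043 to 3331 genes for SST P10, 732 to 2104 for PV P10 (732 and 757 without PV replicates 3 and 2, 2104 without chandelier replicate 1), 2169 to 3884 for chandelier P10 (2169 and 2232 without replicates 2 and 3), 401 to 765 for SST age (401 without P5 replicate 3, 510 and 554 without P10 replicates 1 and 2), 578 to 991 for PV age (578 without P10 replicate 2, 750 and 610 without P5 replicates 1 and 3) and 53 to 283 for chandelier age (53 without P8 replicate 2, and 79, 283 and 115 without P10 replicates 1, 2 and 3). It gave 90 to 128 for the interaction, 2398 to 3483 for P5 against P0, 1724 to 3055 against pyramidal cells (1724 and 1742 without pyramidal replicates 1 and 2) and 5085 to 5417 against oligodendrocytes. Above both, the ranges were 470 to 549 for SST, 132 to 218 for PV and 321 to 897 for chandelier cells (897, 321 and 324 without replicates 1, 2 and 3). None of the 12799 leave-one-out values of 1427 named gene results reversed, and 417 results lost the threshold at least once. A pseudocount of 0.1 lost 106, quantile normalization 107 and the library number block 52. Depth, from 17.9 to 44.4 fragments per FPKM and kilobase, limits what a listed 0 means.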

Other observations

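Isl1, Zic4, Gnrh1 and Fgf15 were chosen after their values were seen. In PV P5, Isl1 was at 30.2, 20.6 and 11.7 FPKM in replicates 1, 2 and 3, Zic4 at 15.3, 16.3 and 7.69, Gnrh1 at 8.29, 16.9 and 4.35, and Fgf15 at 8.52, 13.1 and 4.6. In PV P10 replicate 2, Isl1 was at 4.53 FPKM and Zic4 at 1.24. Isl1 was also at 10.7, 1.97 and 9.14 FPKM in chandelier P8 and at up to 14.4 in interneurons P0, and Zic4 at 10.7, 1.78 and 3.15 in chandelier P8. The SST P10 libraries held Gnb4, with Nr4a2 also known from claustrum neurons, at 808, 828 and 800 FPKM, against 71.5, 66.5 and 87.8 in pyramidal P12.

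Each count was also set against other splits of the same libraries, as planned before the values were seen. In refits as 2 groups, SST P10 called 1216 genes, with 2 of 84 splits as large. Chandelier P10 against the rest called the most, 1320 (1 of 84, with 1216 as the highest other). PV P10 called 119 genes, with 3 of 84 splits as large, the larger ones being those of the other subtypes. Every remaining split mixes subtypes, so these ranks exclude chance for the grouping by subtype as a whole, not for 1 subtype. For P5 against P0 the real split called 2146 and the highest other, SST P5 against the rest, 1224 (1 of 84). For interneurons against pyramidal cells these were 784 and 37 (1 of 100). Other splits mix groups, so chance is excluded only for the grouping as a whole.

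The age comparisons of 3 against 3 libraries have 10 splits, too few for a share under 0.05. The real split called 369 genes in SST cells (highest other 5), 473 in PV cells (4) and 8 in chandelier cells (4), each the largest (1 of 10). Of the 4 chandelier splits that part all 3 same-numbered pairs, the real one called 8 genes and the others 0, and the splits that part 1 pair called at most 4, a sorting chosen after the values were seen. With a replicate block in these refits, the real split called 4 and the other 3 that part all pairs 0, while those that part 1 pair called 78 to 123. Under the block, a split that parts 1 pair compares the libraries of that pair alone. Its count is not comparable with the others, and no conclusion is drawn from it. Of 100 relabellings of the 9 P10 libraries, the real one included, 1 gave as many genes above both other labels as the 417 of SST cells. As many as the 238 of chandelier cells were given by 3. Chance can be excluded there for the labels as a whole, not for 1 subtype by itself. For the 115 of PV cells 7 did, the real one among them, so chance cannot be excluded, and the other 6 each kept the SST or the chandelier libraries together. The highest other was 275 in each case.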
